A study of Gallus gallus with 18 samples.

How the data were processed

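RNA from 3 tissues of chickens was measured on 18 Affymetrix chicken genome arrays, 3 per group in 6 groups. Per the labels, birds were kept at 28 ± 1 °C for 8 days and then either sampled as controls or held at 40 ± 1 °C for 3 h. The labels name the tissues as brain (cerebral cortex), liver and leg muscle, and give 24 birds, 12 male and 12 female, without saying which bird or sex went to which array. Whether RNA of several birds was pooled for an array is not stated in the labels. The controls carry the time label T0 and the heated birds T3, so time of sampling went with heat.

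The deposited table holds 1 intensity per probe set and array on a linear scale, from 1 to 28637. Biotinylated cRNA was made by the authors from total RNA. The software GCOS, version 1.4, is named by the authors without its role, and the summarisation, background correction and scaling between arrays are not given in the sources used here. The table lists 38535 probe sets. The 96 control probe sets were left out, and of the other 38439, 27168 carry 1 gene symbol, 177 carry several and 11094 carry none.

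Intensities were analysed as log2(intensity + 16). Within a tissue the deposited scaling was kept when the arrays' trimmed means, with 2% removed at each end, lay within 10% of each other. This held in brain (highest over lowest 1.07) and muscle (1.04), while liver (1.12) was quantile normalized. Probe sets with a mean below the median probe set of the tissue were left out, which set the limit at intensities of 96.1 in brain, 82.1 in liver and 85.1 in muscle and left 19220 probe sets in each. The 6 bacterial trp control probe sets, a measure of background, read between 6.06 and 97.6. Array medians lay between 79.7 and 99.3, so the lowest tested intensities lie close to background. The number of arrays limits the precision.

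Heat was compared with control within each tissue by limma 3.58.1 in R 4.3.3 (linear model, moderated two-sided test with an intensity trend), with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. Fold changes are taken from the log2 scale with the added 16. Differences in the heat effect between tissues were tested as interaction contrasts over the 18 arrays, on probe sets kept in either tissue. Overlaps of calls were set against the product of the call rates by Fisher's exact test, one-sided. A gene was called separated when the heat values lay outside the range of the control values.

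Before the data were examined, 45 gene lists were fixed, 14 of cell type or tissue markers and 31 of pathways, complexes and stress responses. Of their 1092 symbols, 911 matched a probe set. Lists with at least 5 measured members were tested by camera with a preset correlation of 0.01, on 1 probe set per gene, and adjusted over the lists of a tissue. Camera with an estimated correlation and fry were the other set tests. With arrays split otherwise than by heat, camera with the preset correlation called up to 12 lists in brain, 14 in liver and 16 in muscle. A camera call alone therefore does not tell heat from other splits. A call lost with an estimated correlation does not by itself show that the members of a list were correlated. In brain, the list of ATF4 amino acid response genes had an estimated correlation of -0.056, below the preset value. Its camera call was lost too (adjusted p from 0.0025 to 0.26). The rule for named genes was fixed at the same time. It takes, per tissue, the 6 largest rises and 6 largest falls among separated calls with a gene symbol, the 3 members with the smallest p from each of the 6 lists with the smallest p, and 10 heat shock genes whatever their result. It adds the 4 largest differences in each direction for each pair of tissues, and up to 6 genes called alike in the 3 tissues. Other genes are marked as chosen after their values were seen.

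The steps were tested on simulated data with 200 changed genes per tissue. Normal noise was drawn independently for each probe set and array. Correlation between genes and structure between arrays were not simulated, so the rates below do not cover them. At log2 changes of 0.5, 1 and 2, the share found was 25.4%, 76.1% and 97.0% with the spread of brain, 7.46%, 64.2% and 93.9% with that of liver, and 1.49%, 55.2% and 87.9% with that of muscle. False calls were 12 of 144 in brain, 5 of 115 in liver and 4 of 100 in muscle, and none arose when nothing was changed. For the brain and liver difference, 193 of 200 changes were found with 14 false calls.

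Alternatives fixed before the data were examined were other scalings, pseudocounts of 1 and 64, no filter, a filter at the 75th percentile, a fit over 18 arrays, no intensity trend, array weights, replicate number as a block, 1 probe set per gene, an unadjusted p with a change of 2-fold, and leaving out each array. Chosen after seeing the data were a restriction to probe sets under 4-fold higher in the controls of another tissue, the mean of the hepatocyte markers or the EEF1A 3'/5' ratio as covariates, and leaving out muscle control 3 and muscle heat 3 together. The actin 3'/5' ratio as a covariate for 2 gene lists in brain was also chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Raw image files were not used here.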

Results

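The series asked how acute heat stress alters gene expression in brain, liver and leg muscle of young chickens. Expression was measured on 3 control arrays (28 °C) and 3 heat arrays (40 °C for 3 h) per tissue. Median intensities were 91.6 to 99.3 in brain, 79.7 to 83.7 in liver and 82.7 to 87.9 in muscle. Correlations between arrays of a group ran from 0.976 to 0.993. The 3'/5' intensity ratio of EEF1A, a measure of RNA integrity, ran from 1.21 to 2.30 and was highest in muscle control 3.

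Transcripts of other tissues were present on some arrays and are given here because they were higher on some or all heat arrays of a tissue. Over 10 hepatocyte markers, the median level in brain heat 1 was 10.6% of the liver control level, against 0.90% and 1.49% in brain heat 2 and 3 and 0.34% to 0.54% in the brain controls. The same measure was 28.0% in muscle heat 3 and 1.13% to 4.42% on the other muscle arrays. Over 14 skeletal muscle markers, brain heat arrays held 0.95% to 1.82% of the muscle level and brain controls 0.47% to 0.55%. In liver, muscle markers stood at 1.39% and 1.70% in heat 2 and 3 and at 0.58% to 0.69% on the other arrays. Over 7 neuron markers, muscle heat arrays held 1.10% to 2.61% of the brain level and muscle controls 0.61% to 0.86%. Liver heat 1 and 3 held 1.91% and 1.81% of the neuron marker level, and the other liver arrays 0.99% to 1.20%.

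**Figure D1:**
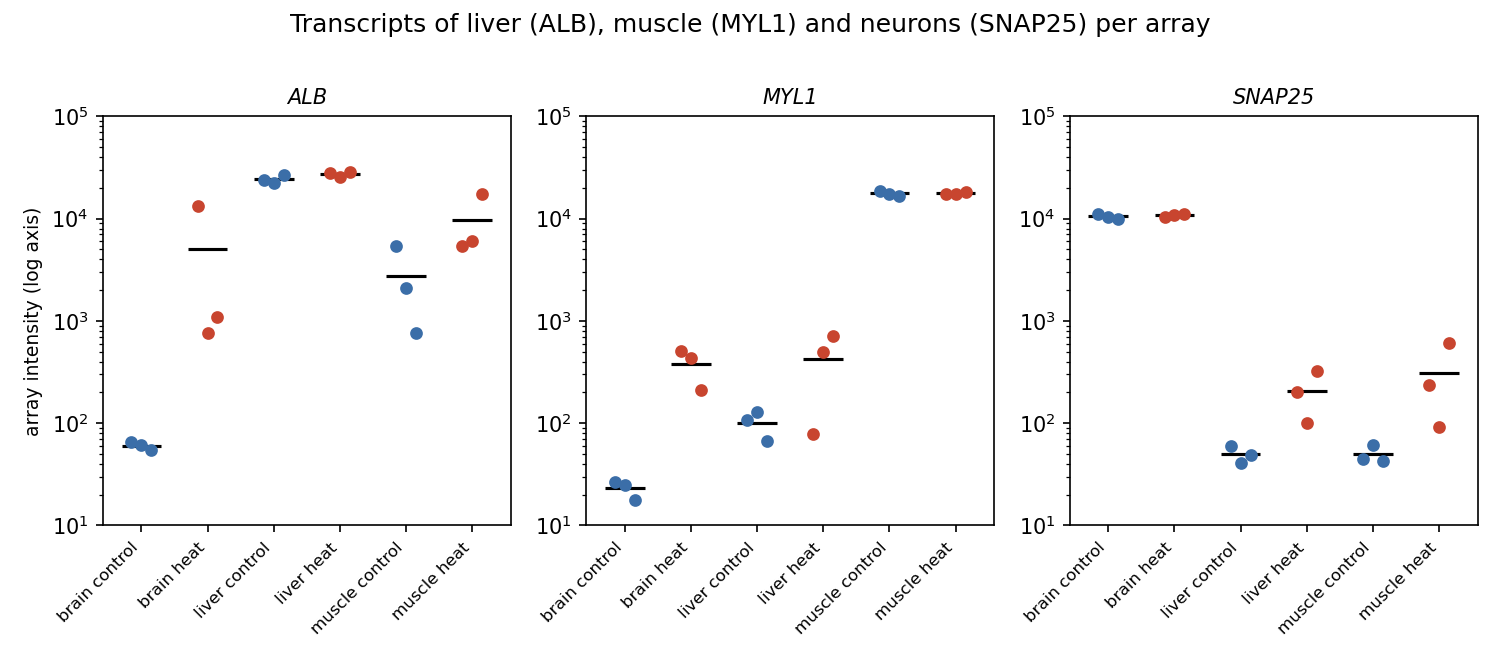
Deposited array intensity on a log axis for ALB (albumin, made by hepatocytes), MYL1 (myosin light chain of skeletal muscle) and SNAP25 (a neuronal synaptic protein) in the 6 groups, with controls in blue, heat in red, 1 point per array and a line at the mean of 3. ALB reached 13260 in brain heat 1 against 54.1 to 65.7 in the brain controls, and SNAP25 reached 607.1 in muscle heat 3 against 42.5 to 61.3 in the muscle controls.

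In brain, 13 of 25 cytosolic and 13 of 27 endoplasmic reticulum chaperones rose with heat, and the others were not called. Both lists shifted by camera and by fry, and neither call held with an estimated correlation (adjusted p = 0.26 with an estimated correlation for each). HSPB9, a small heat shock protein, rose 17.2-fold (log2 4.11, SE 0.32, adjusted p = 0.0021), from an intensity of 290.7 ± 124 to 5049 ± 1422 (SD, n = 3 arrays per group). Its other, more abundant probe set rose by a log2 of 2.93 (SE 0.35, adjusted p = 0.013), a call lost without brain control 1 (adjusted p = 0.076) and without heat 2 (0.068). HSPA2, a member of the HSP70 family, rose 2.82-fold (log2 1.49, SE 0.069, adjusted p = 0.00019), from 4447 ± 89.9 to 12571 ± 697. BAG3, a cochaperone of HSP70, rose 3.73-fold (log2 1.90, SE 0.12, adjusted p = 0.00098). HSPB9 and BAG3 are also abundant in muscle, whose markers were higher on the brain heat arrays. Those arrays held a median of 0.95% to 1.82% of the muscle level over the markers, with no marker above 11.9%. On this probe set HSPB9 had a mean of 8199 in heated muscle. BAG3 read 1930 to 2233 on the brain heat arrays and 7324 to 7924 on the muscle heat arrays. For these 2 genes, the values argue against muscle RNA as the whole source of the rise. The largest falls were in S100A10, a member of the S100 protein family (log2 -1.44, SE 0.37, adjusted p = 0.042), and RAMP2, a receptor accessory protein (log2 -1.38, SE 0.21, adjusted p = 0.019). Their calls held in 1 and 3 of the 6 fits that left out 1 array. On heat 1, 2 and 3, S100A10 read 724, 253 and 230, against 913 to 1109 on the controls. RAMP2 read 218, 128 and 122, against 371 to 493.

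Of 25 measured cytosolic heat shock chaperones, 13 rose, 0 fell and 12 were not called in brain, with a list median of +0.35 on the log2 scale (camera adjusted p = 2.56e-10, fry adjusted p = 0.0039, and adjusted p = 0.26 with an estimated correlation). Adjusted over the list alone, 18 rose and 1 fell. Besides HSPA2 and BAG3, the list includes DNAJA4 (log2 1.29, SE 0.098, adjusted p = 0.0020) and DNAJA1 (log2 0.62, SE 0.12, adjusted p = 0.024), cochaperones of the HSP40 family. HSPH1 of the HSP110 family rose 2.64-fold (SE of log2 0.16, adjusted p = 0.011). The abundant HSP90AA1 and HSPA8 rose by 0.61 (SE 0.077, adjusted p = 0.013) and 0.32 (SE 0.057, adjusted p = 0.024). Of 27 measured endoplasmic reticulum chaperones, 13 rose and 0 fell (median +0.43, adjusted p = 2.20e-08, fry adjusted p = 0.0039, and adjusted p = 0.26 with an estimated correlation). Over the list alone, 17 rose and 1 fell. They include CRELD2 (log2 1.33, SE 0.095, adjusted p = 0.0016), HSPA5, the main HSP70 of this compartment (1.08, SE 0.10, adjusted p = 0.0059), and HSP90B1, its HSP90 (1.47, SE 0.14, adjusted p = 0.0073). Of 15 genes of the amino acid response driven by ATF4, 5 rose and 0 fell (median +0.33, adjusted p = 0.0025, fry adjusted p = 0.0039, and adjusted p = 0.26 with an estimated correlation; 6 and 0 adjusted over the list alone). Among them were MTHFD2, a mitochondrial folate enzyme (log2 0.89, SE 0.12, adjusted p = 0.014), CARS, the cysteinyl-tRNA synthetase (0.85, SE 0.13, adjusted p = 0.019), and ATF4 itself (0.47, SE 0.099, adjusted p = 0.029). For ATF4, 1 of 2 other probe sets tested in brain changed in the same direction. SERPINH1, a collagen chaperone (log2 0.54, adjusted p = 0.058), HSPB1 (0.42, adjusted p = 0.16) and the heat shock factor HSF3 (0.19, adjusted p = 0.23) did not pass.

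**Figure D2:**
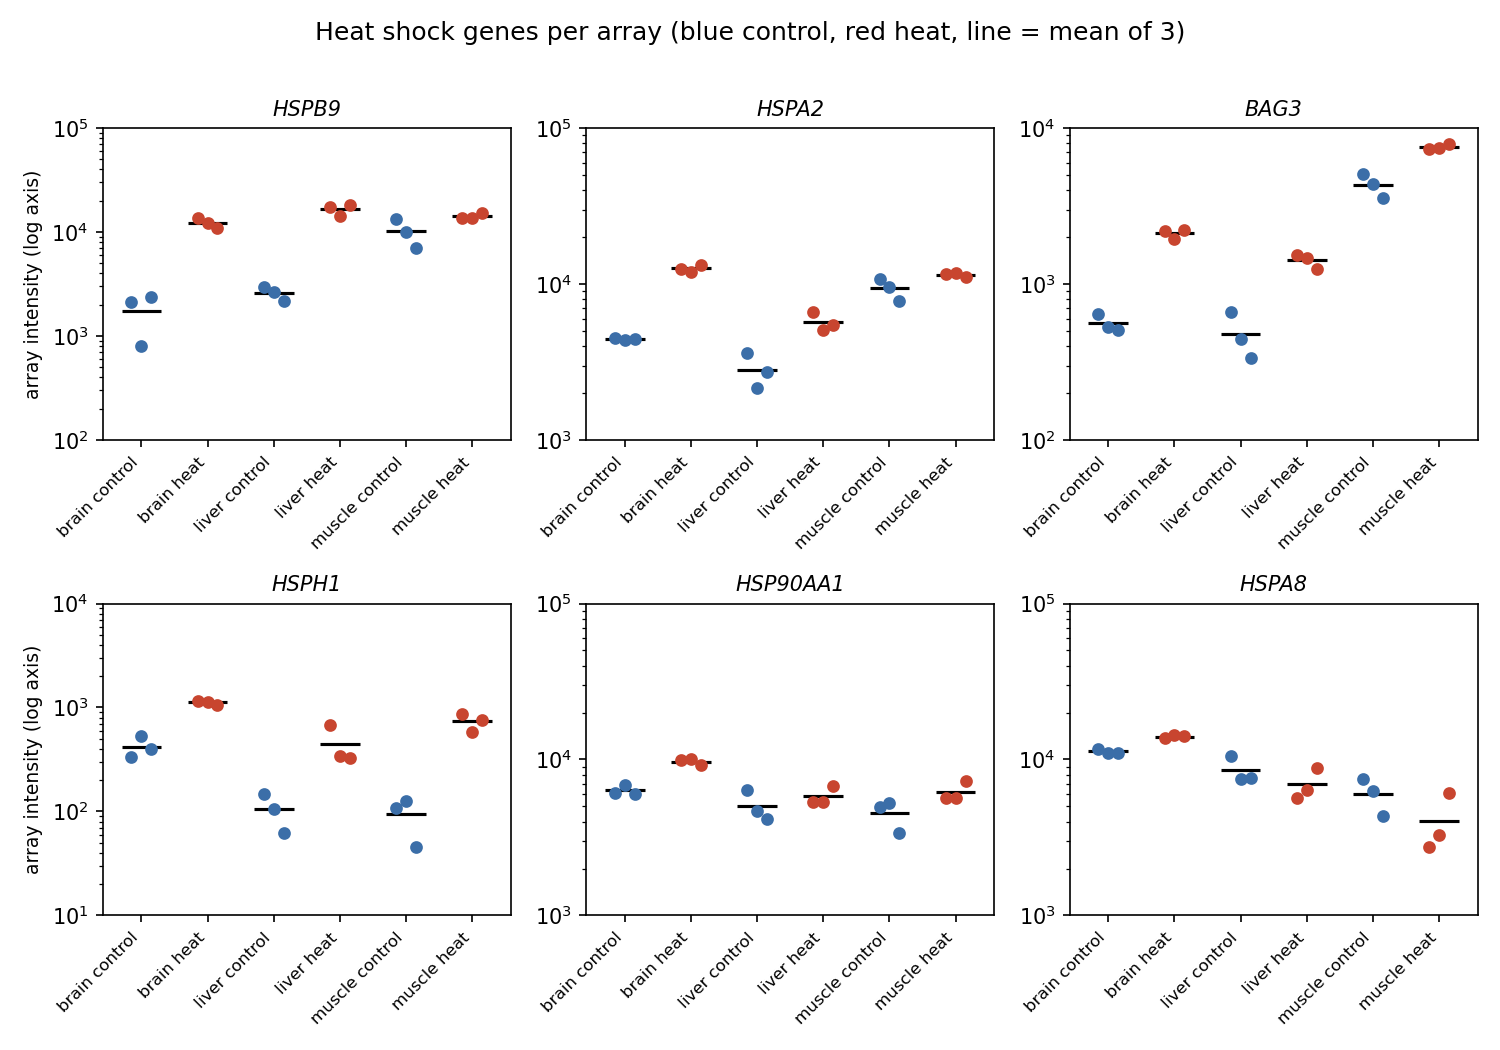
Deposited array intensity on a log axis for 6 heat shock genes in the 6 groups (HSPB9 by its more abundant probe set), with controls in blue, heat in red, 1 point per array and a line at the mean of 3. HSPA2 lay between 11913 and 13302 on the brain heat arrays and between 4348 and 4523 on the brain controls, while HSPA8 on the liver and muscle arrays overlapped between the conditions.

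The lists of oxidative phosphorylation and ribosomal protein genes shifted downward in brain by camera, but not with an estimated correlation (adjusted p = 0.94 with an estimated correlation for each) or by fry (adjusted p = 0.20 and 0.23). Of 54 genes of oxidative phosphorylation, 20 fell, 0 rose and 34 were not called (median -0.48, adjusted p = 2.56e-10). Adjusted over the list alone, 41 fell and 0 rose. Examples are COX8A of cytochrome c oxidase (log2 -1.02, SE 0.23, adjusted p = 0.033) and NDUFB4 and NDUFB9 of complex I (-0.71, SE 0.15, adjusted p = 0.029; -0.63, SE 0.14, adjusted p = 0.033). For NDUFB4, 1 of 2 other probe sets tested in brain changed in the same direction. Of 56 ribosomal protein genes, 4 fell, 0 rose and 52 were not called (median -0.44, adjusted p = 7.87e-10). Over the list alone, 38 fell and 0 rose. RPL31 changed by -0.62 (SE 0.12, adjusted p = 0.024), RPL10A by -0.45 (SE 0.11, adjusted p = 0.039) and RPL23 by -0.68 (SE 0.18, adjusted p = 0.044). Relative to the control mean, the mean of both lists stood at -0.11 in brain heat 1, the array with the most hepatocyte transcripts, and at -0.53 and -0.66 in heat 2 and 3. The 3'/5' ratio of EEF1A was 1.396, 1.32 and 1.36 on brain heat 1, 2 and 3 and 1.47 to 1.56 on the controls, and that of actin was 1.35, 1.17 and 1.08 against 1.33 to 1.39. The lists of the tricarboxylic acid cycle (1 of 17 rose, 2 fell, adjusted p = 0.94) and glycolysis (1 of 22 rose, 1 fell, adjusted p = 0.89) were not called. Of 18 genes of cholesterol synthesis, 3 fell and 0 rose (median -0.26, adjusted p = 0.033, fry adjusted p = 0.16, and adjusted p = 0.94 with an estimated correlation; 6 and 0 adjusted over the list alone). The cholesterol call was also lost with quantile scaling (adjusted p = 0.078), with the mean over a gene's probe sets (0.073), without brain control 3 (0.15) and without brain heat 1 (0.18). Other large falls were in CDC26, a subunit of the anaphase-promoting complex (log2 -1.32, adjusted p = 0.036), and SIX3, a transcription factor of the forebrain (-1.32, adjusted p = 0.020). ID1, an inhibitor of basic helix-loop-helix factors, changed by -1.30 (adjusted p = 0.035), and BOLA3, a mitochondrial iron-sulfur cluster factor, by -1.29 (adjusted p = 0.024). Calls of CDC26, SIX3, ID1 and BOLA3 held in 1, 3, 1 and 2 of the 6 fits that left out 1 array. Like the mean of the oxidative phosphorylation and ribosomal protein lists, S100A10, RAMP2, CDC26, ID1 and BOLA3 fell less in heat 1 than in heat 2 and 3. For these genes RNA integrity was not tested and cannot be told apart from heat. SIX3 read 396, 292 and 364 on heat 1, 2 and 3.

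The largest rises in brain beside HSPB9 were transcripts abundant in liver or muscle. ALB rose by a log2 of 4.88 (SE 0.89, adjusted p = 0.024), the fibrinogen chains FGG and FGB by 4.65 (SE 1.10, adjusted p = 0.036) and 3.79 (SE 1.00, adjusted p = 0.045), and the plasma protein PIT54 by 4.06 (SE 1.02, adjusted p = 0.041). MYL1 rose by 3.27 (SE 0.27, adjusted p = 0.0027). The mean control intensities of ALB, FGG, FGB, PIT54 and MYL1 were 60.4, 18.4, 42.6, 15.6 and 23.01, where bacterial trp controls read up to 65.0 on the brain arrays. The sizes of these rises therefore depend on the constant of 16 added before the logarithm and are not exact folds. The first 4 also rested on heat 1, with changes from 3.60, 3.12, 2.38 and 2.63 without heat 1 to 5.66, 5.79, 4.77 and 5.12 without heat 2. The call of ALB held without heat 1 or heat 3 and those of FGG, FGB and PIT54 without heat 1, and each was lost without any other single array (adjusted p from 0.056 to 0.14). Of 22 acute phase and inflammation genes, 3 rose and 0 fell (median +0.44, adjusted p = 0.0025; 5 and 0 adjusted over the list alone), and these 3 were FGB, FGG and PIT54, secreted by hepatocytes. The list call was lost with an estimated correlation (adjusted p = 0.94 with an estimated correlation) and on probe sets under 4-fold higher in another tissue (adjusted p = 0.43), and it did not pass fry (adjusted p = 0.40).

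In brain, 7 of 41 lists shifted by camera (0 with an estimated correlation, 3 by fry) and 2361 of 19220 probe sets were called, 1258 higher and 1103 lower in heat, with 68 and 40 of them changed by at least 2-fold. With array medians set equal, the split was 918 higher and 1463 lower. At an unadjusted p under 0.05, 6130 probe sets passed against 961 by chance, and 36.5% of probe sets were separated against 10% by chance. The count fell to 10 without brain control 1, 18 without control 3, 20 without heat 2, 810 without control 2 and 880 without heat 3, and rose to 4407 without heat 1. Without brain control 1, control 3 and heat 2, 4927, 4454 and 4141 probe sets still passed an unadjusted p under 0.05 by limma. Of 33 named calls, 7 held without any single array (HSPB9 on its less abundant probe set, HSPA2, BAG3, DNAJA4, CRELD2, HSPA5 and MYL1) and 26 were lost without at least 1 array.

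In liver, camera called lists of lipid metabolism and chaperones, none of which held with an estimated correlation (adjusted p from 0.78 to 0.81 with an estimated correlation). Single genes of glucose metabolism changed as well. PCK1, which commits oxaloacetate to gluconeogenesis, rose by a log2 of 4.71 (SE 0.86, adjusted p = 0.015), from a quantile-normalized intensity of 162.6 ± 230 to 2467 ± 856 (SD, n = 3 arrays per group). The size of this rise is not exact, since its deposited intensities were 409.8, 8.09 and 53.1 on the controls and trp controls read up to 97.6 on the liver arrays. Without single arrays its log2 change ran from 3.76 to 5.85, and the call was lost without liver control 3 (adjusted p = 0.053) and without heat 1 (0.064). The list of gluconeogenesis and glycogen genes was not called (3 of 19 rose, 4 fell, median -0.16 and mean +0.095, adjusted p = 0.45), nor was glycolysis (1 of 24 rose, 4 fell, adjusted p = 0.14). HSPB9 rose 23.6-fold (log2 4.56, SE 0.14, adjusted p = 4.08e-06), from 563.2 ± 84.7 to 13577 ± 1406, and by a log2 of 2.59 on its other probe set (SE 0.13, adjusted p = 9.62e-05). SQLE and HSD17B7, enzymes of sterol synthesis, were 7.06-fold (log2 -2.82, SE 0.41, adjusted p = 0.0079) and 6.76-fold lower in heat (log2 -2.76, SE 0.14, adjusted p = 9.62e-05). The xenobiotic enzyme CYP1A1 was 8.63-fold lower (log2 -3.11, SE 0.31, adjusted p = 0.0030).

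Of 18 measured genes of cholesterol synthesis, 13 fell, 0 rose and 5 were not called in liver (median -0.97, adjusted p = 1.86e-05, fry adjusted p = 0.022, and adjusted p = 0.78 with an estimated correlation). Adjusted over the list alone, 14 fell and 3 rose. NSDHL and LSS, which act late in the pathway, changed by -2.09 (SE 0.22, adjusted p = 0.0039) and -2.07 (SE 0.23, adjusted p = 0.0044). Of 22 genes of fatty acid synthesis, 6 fell and 0 rose (median -0.41, adjusted p = 0.00068, fry adjusted p = 0.059, and adjusted p = 0.78 with an estimated correlation). Over the list alone, 11 fell and 0 rose. Among them were SCD, the stearoyl-CoA desaturase (log2 -1.52, SE 0.24, adjusted p = 0.0099), AGPAT2, an enzyme of glycerolipid synthesis (-0.92, SE 0.15, adjusted p = 0.012), and FASN, the fatty acid synthase (-0.84, SE 0.14, adjusted p = 0.012). THRSP, a lipogenic nuclear protein, changed by -2.53 (SE 0.45, adjusted p = 0.014). Of 35 cell cycle genes, 12 fell and 0 rose (median -0.38, adjusted p = 0.00048, fry adjusted p = 0.048, and adjusted p = 0.78 with an estimated correlation; 16 and 0 adjusted over the list alone). MCM3, MCM5 and MCM2, subunits of the replicative helicase, changed by -1.78 (SE 0.13, adjusted p = 0.0011), -1.57 (SE 0.17, adjusted p = 0.0039) and -1.43 (SE 0.13, adjusted p = 0.0022). The 17 hepatocyte markers measured had a median change of +0.05 with none called (adjusted p = 0.33).

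**Figure D3:**
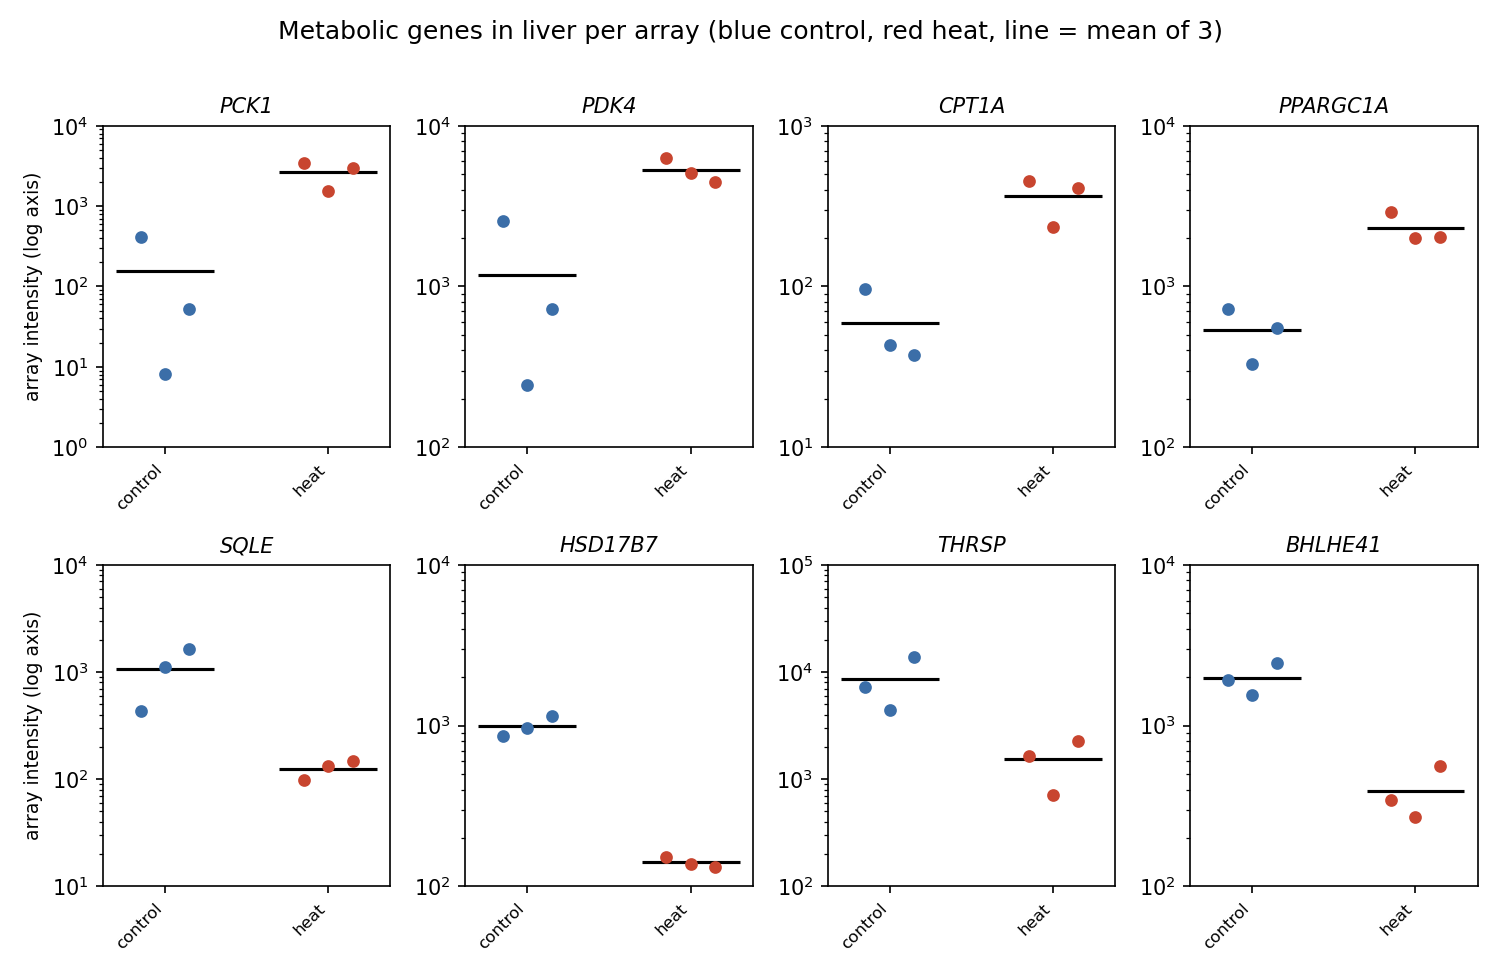
Deposited array intensity on a log axis for 8 genes on the 6 liver arrays, with controls in blue, heat in red, 1 point per array and a line at the mean of 3. PCK1 lay between 1533 and 3399 on the heat arrays and between 8.09 and 409.8 on the controls, and HSD17B7 between 131.0 and 153.2 against 859.9 to 1141.

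The list of fatty acid oxidation and ketogenesis shifted upward in liver by camera, but not with an estimated correlation (adjusted p = 0.81 with an estimated correlation) or by fry (adjusted p = 0.14). Of 20 genes in it, 7 rose, 1 fell and 12 were not called (median +0.33, adjusted p = 0.0096). Adjusted over the list alone, 9 rose and 2 fell. CPT1A, which admits long-chain fatty acids to mitochondria, rose by a log2 of 2.35 (SE 0.31, adjusted p = 0.0061; the size is not exact, with control intensities of 94.9, 43.6 and 37.5 near those of trp controls), the coactivator PPARGC1A by 1.99 (SE 0.28, adjusted p = 0.0071) and the isomerase ECI2 by 1.31 (SE 0.11, adjusted p = 0.0022). The member that fell, ECI1, is another isomerase of the pathway (log2 -0.70, adjusted p = 0.012; chosen after its value was seen). PDK4, which restrains pyruvate oxidation, rose by 2.65 (SE 0.67, adjusted p = 0.036). Its change ran from 1.83 without liver control 2 to 3.51 without control 1, and its call held only without control 1 and was lost without each other array (adjusted p from 0.065 to 0.12). MPC1L, related to the mitochondrial pyruvate carrier, rose by 2.75 (SE 0.41, adjusted p = 0.0092). Of 54 genes of oxidative phosphorylation, 6 fell and 0 rose (median -0.28, adjusted p = 0.0011, fry adjusted p = 0.29, and adjusted p = 0.81 with an estimated correlation; 6 and 0 adjusted over the list alone). NDUFS8 and NDUFV1 of complex I changed by -0.70 (SE 0.16, adjusted p = 0.027) and -0.52 (SE 0.11, adjusted p = 0.021), and ATP5B of ATP synthase by -0.39 (SE 0.094, adjusted p = 0.032). The oxidative phosphorylation call was also lost with the mean over a gene's probe sets (adjusted p = 0.053) and without liver heat 3 (0.063).

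Of 24 cytosolic heat shock chaperones in liver, 8 rose, 1 fell and 15 were not called (median +0.32, adjusted p = 0.036). Over the list alone, 11 rose and 4 fell. The list call was lost with an estimated correlation (adjusted p = 0.78 with an estimated correlation), without liver control 3 (0.087), without liver heat 3 (0.058) and with the mean over a gene's probe sets (0.053), and it did not pass fry (0.059). HSPH1 rose by a log2 of 1.87 (SE 0.31, adjusted p = 0.012), BAG3 by 1.46 (SE 0.24, adjusted p = 0.012), HSPA2 by 0.94 (SE 0.18, adjusted p = 0.017) and SERPINH1 by 0.63 (SE 0.12, adjusted p = 0.017). The member that fell was HSP90AB1, a constitutive HSP90 (log2 -0.68, adjusted p = 0.022; chosen after its value was seen). HSPA8 (log2 -0.36, adjusted p = 0.18), HSP90AA1 (0.14, adjusted p = 0.56), DNAJA1 (0.13, adjusted p = 0.60), HSPB1 (0.67, adjusted p = 0.16) and HSF3 (0.43, adjusted p = 0.14) did not pass. Of 24 genes of ubiquitin ligation, atrophy and autophagy, 7 rose and 0 fell (median +0.19, adjusted p = 0.015; 8 and 1 adjusted over the list alone; adjusted p = 0.78 with an estimated correlation and 0.022 by fry). Of 30 proteasome genes, 6 fell and 1 rose (median -0.21, adjusted p = 0.0096; 10 and 1 adjusted over the list alone; adjusted p = 0.81 with an estimated correlation and 0.059 by fry). The proteasome genes PSMD3, PSMD2 and PSMB4 changed by -0.91 (SE 0.17, adjusted p = 0.015), -0.79 (SE 0.13, adjusted p = 0.013) and -0.61 (SE 0.11, adjusted p = 0.015), and the list call was lost under the deposited scaling (adjusted p = 0.095) and with array medians set equal (0.087).

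Further large changes in liver were in CYP1A2, related to CYP1A1 (log2 -2.19, SE 0.41, adjusted p = 0.016), and BHLHE41, a repressor tied to the circadian clock (-2.43, SE 0.26, adjusted p = 0.0039). RTN1, a reticulon abundant in brain, rose by 2.47 (SE 0.33, adjusted p = 0.0061; not an exact size, from a mean control intensity of 41.7), on arrays where neuron markers were also higher in heat 1 and 3. Of 13 adipose and connective tissue markers, 4 rose and 0 fell (median +0.32, adjusted p = 0.024; 5 and 0 adjusted over the list alone; adjusted p = 0.81 with an estimated correlation and 0.18 by fry). The marker call was lost on probe sets under 4-fold higher in another tissue (adjusted p = 0.13), with the mean over a gene's probe sets (0.076), without liver control 3 (0.093), without heat 2 (0.051) and without heat 3 (0.055).

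In liver, 9 of 38 lists shifted by camera (0 with an estimated correlation, 4 by fry) and 2512 of 19220 probe sets were called, 1334 higher and 1178 lower in heat, with 193 and 158 of them changed by at least 2-fold. The split was 1894 higher and 837 lower under the deposited scaling, and 1631 and 778 with array medians set equal. At an unadjusted p under 0.05, 6240 probe sets passed against 961 by chance, and 37.2% were separated against 10% by chance. The count was 592 without liver control 2, 487 without control 3, 539 without heat 1 and 1066 without heat 3. In these fits 4783, 4618, 4938 and 5316 probe sets still passed an unadjusted p under 0.05 by limma. Of 33 named calls, 19 held without any single array, among them HSPB9, HSD17B7, CPT1A and the 3 MCM genes, and 14 were lost without at least 1 array.

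**Figure D4:**
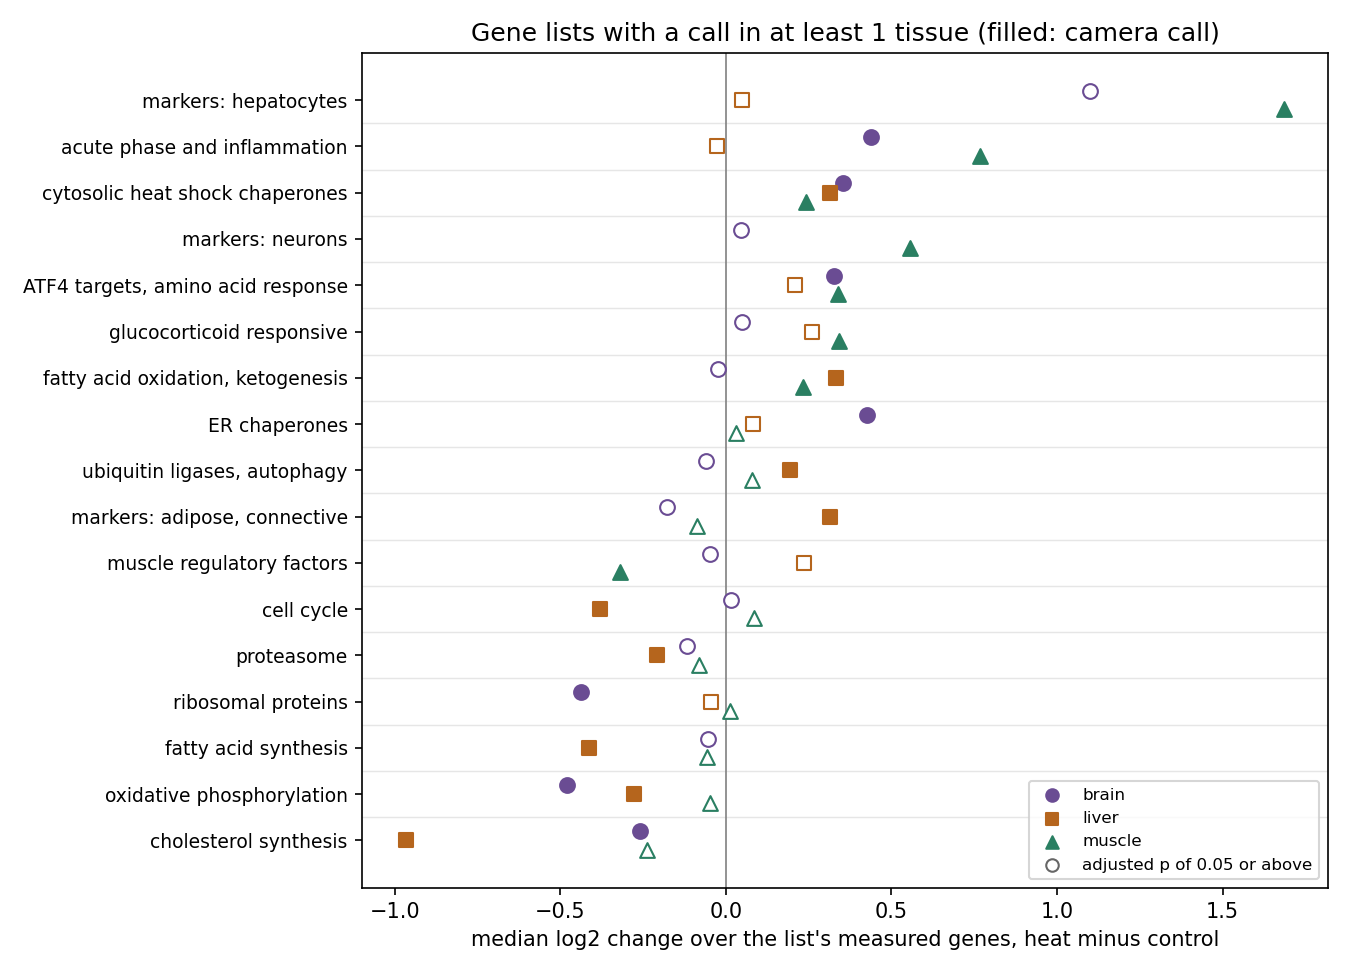
Median log2 change (heat minus control) over the measured genes of each list with a camera call in at least 1 tissue, for brain (circles), liver (squares) and muscle (triangles), filled where the adjusted p was under 0.05 with the preset correlation (0 with an estimated correlation). Cytosolic heat shock chaperones had medians of +0.35, +0.32 and +0.24 in brain, liver and muscle, and cholesterol synthesis genes had -0.26, -0.97 and -0.24, without a call in muscle.

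In muscle, 1 probe set passed, that of ASB2, a substrate receptor of a ubiquitin ligase. ASB2 rose 8.17-fold (log2 3.03, SE 0.22, adjusted p = 0.022), from 245.6 ± 58.7 to 2113 ± 416 (SD, n = 3 arrays per group). The next genes did not pass. They include HSPH1 (log2 2.85, SE 0.32, adjusted p = 0.068), PDK4 (2.11, SE 0.31, adjusted p = 0.070), UCP3, a mitochondrial uncoupling protein (1.48, SE 0.19, adjusted p = 0.068), and DNAJB5 of the HSP40 family (-1.36, SE 0.20, adjusted p = 0.070).

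In muscle, camera called 8 of 42 lists, although 0 of their members were called over all probe sets. Of these lists, 0 held with an estimated correlation (adjusted p from 0.86 to 0.99 with an estimated correlation) and 0 passed fry. Of 26 cytosolic heat shock chaperones (median +0.24, camera adjusted p = 0.0081, fry adjusted p = 0.58, and adjusted p = 0.99 with an estimated correlation), 9 rose and 2 fell adjusted over the list alone, with BAG3 (log2 0.82, adjusted p = 0.081 over all probe sets) and the HSP90 cochaperone FKBP5 (0.75, adjusted p = 0.098) beside HSPH1. Of 20 fatty acid oxidation genes (median +0.23, adjusted p = 0.0081, fry adjusted p = 0.51, and adjusted p = 0.99 with an estimated correlation), 4 rose and 0 fell adjusted over the list alone, with the acyl-CoA synthetase ACSL1 (log2 1.56, adjusted p = 0.090 over all probe sets) beside PDK4 and UCP3. Of 12 glucocorticoid-responsive genes (median +0.34, adjusted p = 0.0081, fry adjusted p = 0.29, and adjusted p = 0.86 with an estimated correlation), 4 rose and 0 fell adjusted over the list alone, and PDK4 and FKBP5 belong to this list too. Of 14 genes of the amino acid response (median +0.34, adjusted p = 0.048, fry adjusted p = 0.29, and adjusted p = 0.86 with an estimated correlation), 6 rose and 1 fell adjusted over the list alone. Their values over all probe sets included CHAC1, which degrades glutathione (log2 1.51, adjusted p = 0.070), the amino acid transporter SLC38A2 (0.66, adjusted p = 0.13) and MTHFD2 (-0.56, adjusted p = 0.12). Of 15 muscle regulatory factors (median -0.32, adjusted p = 0.021, fry adjusted p = 0.32, and adjusted p = 0.86 with an estimated correlation), 0 rose and 2 fell adjusted over the list alone, the growth inhibitor MSTN (log2 -1.06, adjusted p = 0.11 over all probe sets) and the actin-binding XIRP1 (-1.03, adjusted p = 0.083). ANKRD1 in the same list stood at -0.91 (adjusted p = 0.19). The amino acid response call was lost without control 2 (adjusted p = 0.13), without control 3 (0.077) and on probe sets under 4-fold higher in another tissue (0.46), fatty acid oxidation without control 2 (0.077), muscle regulatory factors without control 1 (0.13), and glucocorticoid-responsive genes on the restricted probe sets (0.061).

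Lists with transcripts of other tissues were called in muscle by camera as well. Hepatocyte transcripts did not follow heat on each array. Over 10 hepatocyte markers, heat 1 and 2 held 3.98% and 4.08% of the liver level, within the 1.13% to 4.42% of the controls, and heat 3 held 28.0%. The 15 hepatocyte markers had a median of +1.68 (adjusted p = 0.00074), the 6 neuron markers +0.56 (adjusted p = 0.021) and the 25 acute phase and inflammation genes +0.77 (adjusted p = 0.045), each with 0 calls over all probe sets and adjusted p = 0.99 with an estimated correlation. By fry their adjusted p were 0.63, 0.58 and 0.63. Adjusted over the list alone, 0 hepatocyte markers, 2 neuron markers and 2 acute phase and inflammation genes rose and 0 fell. The last 2 were NFKB1 and NFKBIA of the NF-kappa-B pathway (log2 0.86 and 0.77, adjusted p = 0.083 and 0.12 over all probe sets), and SOCS3, an inhibitor of cytokine signalling, stood at -1.07 (adjusted p = 0.16). Leaving out muscle control 3 and muscle heat 3, the arrays with the least and the most hepatocyte transcripts, gave adjusted p = 0.36 for hepatocyte markers, 0.13 for cytosolic chaperones, 0.55 for acute phase and inflammation and 0.068 for neuron markers. The acute phase call was also lost without control 2 (adjusted p = 0.13), control 3 (0.12) or heat 3 (0.25) alone and on probe sets under 4-fold higher in another tissue (0.93, with a median of -0.08), and the neuron marker call without control 1 (0.073), control 2 (0.079) or heat 3 (0.084).

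The other fixed heat shock genes did not pass in muscle. Their log2 changes were 0.30 for HSPA2 (adjusted p = 0.29), -0.64 for HSPA8 (0.36), 0.46 for HSP90AA1 (0.29), 0.18 for DNAJA1 (0.56), 0.53 and 1.53 for the more and the less abundant probe set of HSPB9 (0.27 and 0.076), 0.03 for HSPB1 (0.90), 0.34 for SERPINH1 (0.39) and 0.30 for HSF3 (0.39). Muscle controls already held high levels of several, with 10133 ± 3112 for HSPB9 and 9356 ± 1502 for HSPA2. At an unadjusted p under 0.05, 3101 of 19220 probe sets passed against 961 by chance, and 21.8% were separated against 10% by chance. The count of calls by limma was 0 without control 2, control 3 or heat 2 (2458, 2244 and 1840 at an unadjusted p under 0.05), 2 without control 1 and 8 without heat 1, and the adjusted p of ASB2 without those arrays was 0.11, 0.084, 0.19, 0.033 and 0.041.

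The difference between tissues was tested directly. The heat effect differed for 394 of 23128 probe sets between brain and liver (213 above, 181 below in brain), for 78 of 22861 between brain and muscle (44 and 34) and for 210 of 21692 between liver and muscle (105 and 105). With array medians set equal, the splits were 127 and 246 for brain and liver and 159 and 68 for liver and muscle. HSPB9 rose more in brain than in muscle (difference 2.58, SE 0.41, adjusted p = 0.013) and more in liver than in muscle (3.03, SE 0.41, adjusted p = 0.0024). HSPA2 rose more in brain than in muscle (1.19, SE 0.21, adjusted p = 0.019), whereas its difference between brain and liver (0.55, SE 0.21, adjusted p = 0.20) did not pass. ASB2 rose more in muscle than in brain (brain minus muscle -2.86, SE 0.23, adjusted p = 1.51e-05) and more than in liver (liver minus muscle -3.16, SE 0.23, adjusted p = 3.70e-06). In liver compared with brain, PPARGC1A rose more (brain minus liver -2.06, SE 0.36, adjusted p = 0.0099) and SQLE fell more (2.72, SE 0.53, adjusted p = 0.018). Counts moved with single arrays, from 122 without brain heat 2 to 634 without brain heat 1 for brain and liver, from 14 to 307 without the same arrays for brain and muscle, and from 126 without muscle heat 2 to 256 without muscle heat 1 for liver and muscle.

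Brain and liver shared more calls than independent calls would give. Of 15312 probe sets tested in both, 244 were higher in both against 71.0 if independent (Fisher's exact test, p = 1.34e-72) and 241 were lower in both against 61.7 (p = 7.30e-84). In the opposite sense, 2 were higher in brain and lower in liver, and 10 were lower in brain and higher in liver. Shared rises included HSPB9, BAG3, HSPH1, HSPA2 and PDK4. PDK4 rose by a log2 of 1.79 in brain (adjusted p = 0.024) and 2.65 in liver, a call lost without 5 of the 6 liver arrays. Its mean control intensity was 146.7 in brain, 1176 in liver and 2824 in muscle. Markers of liver and muscle were higher on the brain heat arrays, so its brain rise cannot be told apart from RNA of those tissues. Probe sets are not independent of each other, nor are tissues if their arrays hold the same birds, which the labels do not state. With 1 call in muscle, 0 probe sets were called in the 3 tissues. Log2 changes correlated at 0.48 between brain and liver, 0.52 between brain and muscle and 0.55 between liver and muscle. These correlations include transcripts of other tissues that were higher on some heat arrays. The total of 485 was 6 without brain control 1 or brain heat 2, 7 without brain control 3, 71 without liver control 3, 84 without liver control 2 or liver heat 1, 162 without liver heat 3, 199 without brain control 2 and 206 without brain heat 3. With quantile scaling of brain and muscle and deposited scaling of liver the split was 357 higher and 198 lower.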

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

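The tests of liver RNA carried into brain, of short transcripts as the whole cause, of RNA integrity in brain, of fewer hepatocytes and of splits applied to the tissues alike were chosen only after the result was seen. The heat effect differed between tissues, by a test of the difference itself, for 394 probe sets between brain and liver, 78 between brain and muscle and 210 between liver and muscle.

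Between brain and liver (brain minus liver, log2), the largest differences were 4.84 for ALB, 3.19 for CYP1A1, 2.72 for SQLE and 2.27 for PPP1R3C, a glycogen-targeting subunit. In the other direction they were -3.11 for RTN1, -2.57 for MPC1L, -2.14 for EEF1A2, an elongation factor of neurons and muscle, and -2.06 for PPARGC1A. Between brain and muscle (brain minus muscle), they were 2.91 for MYL1, 2.58 for HSPB9, 1.997 for TET2, an enzyme of DNA demethylation, and 1.72 for the stress-responsive factor ATF3. In the other direction they were -2.86 for ASB2, -1.73 for PFKFB3, which raises glycolysis, -1.53 for the kinase PAK6 and -1.52 for UCP3. Between liver and muscle (liver minus muscle), they were 3.03 for HSPB9, 2.47 for MPC1L, 2.43 for the mitochondrial carrier SLC25A25 and 2.41 for TET2. In the other direction they were -3.16 for ASB2, -2.61 for CYP1A2, -2.51 for CYP1A1 and -2.48 for the epithelial factor ELF3. ALB, RTN1, EEF1A2 and MYL1 are abundant in a tissue other than the one in which they rose. The sizes for ALB, MYL1, RTN1, EEF1A2 and PPP1R3C are not exact, since in 1 tissue their control or heat mean was at the level of the trp controls. CYP1A1, ATF3 and UCP3 in brain and CYP1A2 and ELF3 in muscle were at that level in both conditions, so their change there was not measured above background and their differences and ranks rest on the other tissue.

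Transcripts of liver were high in heat-stressed brain, above all in heat 1. Of 119 liver-enriched probe sets outside the gene lists, 87.4% were at least 2-fold above the brain control mean in heat 1, against 3.36% in heat 2 and 13.4% in heat 3. In heat 1 the hepatocyte markers stood at 4.43% to 54.8% of their liver level, with ALB at 13260. This is consistent with liver RNA carried into that sample, and the labels name no sort of cells. Induction of acute phase genes in the brain itself stays open, since 75% (9 of 12) of the liver-enriched acute phase genes lay above liver-enriched probe sets of like level in heat 1, a number too small to decide.

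The lists of oxidative phosphorylation and ribosomal protein genes had a median log2 change of -0.45 in brain over 110 genes, of which 20 and 4 were called lower, and neither list call held with an estimated correlation (adjusted p = 0.94) or by fry (0.20 and 0.23). A dependence on high expression is argued against by 0 of 10000 random lists matched on level with a median as low (lowest -0.13), and liver RNA by a median of -0.63 without heat 1. A loss of short transcripts may contribute, because the 925 other genes with the shortest spans had a median of -0.25. Among 10000 lists matched on gene span and level, 0 had a median as low (lowest -0.25). Gene span is not transcript length, which was not measured, so a loss of short transcripts as the whole cause is not decided. RNA integrity cannot be told apart from heat, since the EEF1A 3'/5' ratios of the heat arrays (1.396, 1.32 and 1.36) lay below those of the controls (1.47 to 1.56), and with the actin ratio as a covariate the heat effect on the mean of both lists went from -0.43 (95% interval -0.90 to 0.035) to -0.13 (-0.40 to 0.14). A response to heat stays open, untested.

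In heat-stressed liver, 13 of 18 genes of cholesterol synthesis and 6 of 22 of fatty acid synthesis fell, with list calls that did not hold with an estimated correlation (adjusted p = 0.78) and of which cholesterol synthesis passed fry (0.022) and fatty acid synthesis did not (0.059). The hepatocyte markers did not fall as a set, with a median change of +0.047 (log2), 9 of 17 positive, 8 negative and 0 called. That median is the value of ALB, among the highest intensities of the liver arrays, which quantile normalization sets nearly alike. Fewer hepatocytes as a cause are therefore not decided by that median. In deposited intensities, the liver transcripts APOB and AHSG read 7248 to 10120 and 14048 to 19685 in heat, against 5344 to 8069 and 15946 to 18689 in controls. SQLE read 97.5 to 146.3 against 434.2 to 1657. With 0 of 17 markers called, these values argue against fewer hepatocytes as the whole cause of the fall in cholesterol synthesis genes. A smaller loss stays open. The time of day of sampling cannot be told apart from heat, since the labels give the controls as T0 and the heated birds as T3. Of 6 core clock genes measured, 2 passed in liver, ARNTL (log2 0.63, adjusted p = 0.034) and CRY1 (0.97, adjusted p = 0.025), and feeding during the heat was not recorded in the labels.

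The 6 arrays of a tissue can be split in 10 ways, the real split included, too few for a share under 0.05. The real split called 2361 probe sets in brain (highest other 2, with 1 of 10 as large), 2512 in liver (highest other 0, with 1 of 10) and 1 in muscle (highest other 169, with 2 of 10). The split that called 169 set muscle control 1 with heat 2 and heat 3 and points to a structure of the muscle samples. These 3 arrays had the lowest 3'/5' ratios of EEF1A (1.53, 1.58 and 1.63, against 1.82 to 2.30 on the other muscle arrays) and of actin (2.004, 2.36 and 2.41, against 2.93 to 3.43), so this split went with measures of RNA integrity, and with the EEF1A ratio as a covariate the real split called 1. The real split shifted 7 gene lists in brain (highest other 12, with 6 of 10 as large), 9 in liver (14, with 7 of 10) and 8 in muscle (16, with 7 of 10). The number of lists called by camera with the preset correlation therefore does not tell heat from other splits of the arrays.

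For the differences between tissues, chance was not excluded, and the regroupings cannot decide about it. No regrouping keeps the heat effects of both tissues while removing the difference between them. Of 100 regroupings, the real one included, 7 gave as many probe sets as the real 394 for brain and liver (highest other 5549), 9 as many as 78 for brain and muscle (4135) and 11 as many as 210 for liver and muscle (5566). Regroupings that kept 1 tissue as labelled, or the second tissue with control and heat exchanged, made up 6, 5 and 9 of these. They hold that tissue's own heat effect and gave the highest counts of 5549, 4135 and 5566. With neither tissue as labelled or exchanged, 0 of 80, 3 of 79 and 1 of 77 gave as many (highest 8, 246 and 1810). For the pairs with muscle, counts several times the real one point to a structure of the samples. Of probe sets called in more than 1 tissue, 2 of 100 regroupings gave as many as the real 485 (highest other 485, with brain and liver as labelled, and 44 with either of them regrouped). These regroupings take the tissues as independent, and since other splits called at most 2 probe sets in brain and 0 in liver, they leave those 2 tissues little to share. With the same split applied to the 3 tissues, as shared birds would need, 1 of 10 gave as many (highest other 0), too few for a share under 0.05, so chance stays open.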

How the results depend on the processing

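The alternatives on transcripts of other tissues, on the EEF1A ratio and on leaving out muscle control 3 and heat 3 together were chosen only after the result was seen. Counts named first are those reported, and except where stated the cause was not tested. In brain, the 2361 calls became 1482 in a fit over 18 arrays, 6922 with array weights, 3765 with the hepatocyte marker mean as a covariate, 933 with 1 probe set per gene (fewer tests) and 139 at an unadjusted p with a 2-fold change (another criterion). In liver, the 2512 calls became 3812, 5002, 1636 and 383 under the same settings except the covariate. In muscle, the 1 call became 1739, 173, 29 and 248, with 2 under the covariate, 3 with quantile scaling, 2 with a pseudocount of 64, 2 with no filter, 52 with the 75th percentile filter, 39 on probe sets under 4-fold higher in another tissue and 0 without control 3 and heat 3 (1872 at an unadjusted p under 0.05 by limma). ASB2 kept its direction under each setting tried, with adjusted p from 2.54e-08 to 0.27.

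For gene lists, an estimated correlation gave 0 calls in brain, liver and muscle, against 11, 14 and 10 at an unadjusted p under 0.05 by camera with the preset correlation, and fry gave 3, 4 and 0. In liver, the list of ubiquitin ligation, atrophy and autophagy had an estimated correlation of -0.0055, below the preset 0.01, and lost its call too. The 0 calls therefore do not by themselves show that correlation within lists undid the calls. No filter gave 11 lists in brain. The count of lists in muscle was 3 on probe sets under 4-fold higher in another tissue and 5 without control 3 and heat 3. Differences between tissues became 598, 178 and 316 for brain and liver, brain and muscle and liver and muscle with a pseudocount of 64, and 523, 27 and 39 when fitted on the 12 arrays of each pair. Probe sets called in more than 1 tissue (485) became 288 with no filter, 1114 in the fit over 18 arrays and 60 at an unadjusted p with a 2-fold change.

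Leaving out 1 array gave 10 to 4407 calls in brain, 487 to 2395 in liver and 0 to 8 in muscle, and 6 to 10, 8 to 14 and 5 to 9 lists. Differences ranged over 122 to 634, 14 to 307 and 126 to 256, and probe sets called in more than 1 tissue over 6 to 665. The lists moved most without liver heat 1 (14) and muscle control 2 (5). For brain and liver the difference was 150, 134 and 178 without brain control 1, 2 and 3, 634, 122 and 159 without brain heat 1, 2 and 3, 210 and 218 without liver control 2 and 3 and 172 without liver heat 1. For brain and muscle it was 22, 44 and 32 without brain control 1, 2 and 3, 307 and 14 without brain heat 1 and 2 and 118 without muscle heat 1. For liver and muscle it was 133 without liver control 3 or liver heat 1 and 126 without muscle heat 2.

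Replicate number did not pair control with heat: of 9 pairs, 2 had a correlation of residuals above 0.1 (highest 0.37). Between tissues, 12 of 18 pairs of the same number did (highest 0.50), and in 11 of the 18 the own number was the highest, so the tissues are not shown to be independent. With the number as a fixed block within a tissue, which pairs control with heat, calls were 505 in brain, 3094 in liver and 0 in muscle. In muscle, 2509 probe sets passed an unadjusted p under 0.05 by limma with this block. It left 139 probe sets called in more than 1 tissue. The differences were fitted otherwise, with the number within a condition as a random block across tissues. They were 532 for brain and liver, 142 for brain and muscle and 313 for liver and muscle.

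DNAJA1, not called in liver, turned to -0.033 without liver control 3. HSPB1, not called in muscle, turned to -0.019 with the hepatocyte covariate, -0.00217 without muscle control 2 and -0.0064 without muscle heat 1, the lowest of its leave-one-out values, of which the highest was 0.098 without muscle heat 2. Of the named genes' results under other settings, 497 in brain, 597 in liver and 457 in muscle kept direction and side of the threshold, 128, 39 and 5 fell short of it and 3, 1 and 33 newly passed. Of the list results, 96, 117 and 95 were kept, 16, 27 and 38 fell short, and the median of acute phase and inflammation in muscle turned to -0.080 on probe sets under 4-fold higher in another tissue (adjusted p = 0.93, range over its alternatives 0.0047 to 0.99). Of the named differences, 145 between brain and liver, 144 between brain and muscle and 148 between liver and muscle were kept, and 22, 23 and 20 fell short. Counts within 1.5 times those reported are not listed. Intensities near background limit what can be called, since trp controls read up to 97.6.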

Other observations

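The test of shared birds was chosen only after the result was seen, and the genes in the next paragraphs were chosen after their values were seen. In liver, genes of the thyroid and growth axis went both ways, and the list was not called (4 of 15 rose, 1 fell, camera adjusted p = 0.21). DIO3, which inactivates thyroid hormone, rose by a log2 of 1.71 (adjusted p = 0.029), IRS2, an adaptor of the insulin receptor, by 1.53 (adjusted p = 0.014) and IGFBP1, which binds insulin-like growth factors, by 1.46 (adjusted p = 0.032). Of 24 genes of xenobiotic and bile acid metabolism, 7 fell and 2 rose without a list call (adjusted p = 0.080), with BAAT, which conjugates bile acids, at -1.25 (adjusted p = 0.0060). LEAP2, a liver peptide, changed by -1.90 (adjusted p = 0.0022).

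In brain, 6 of 29 genes of ion channels and synaptic signalling rose and 2 fell without a list call (adjusted p = 0.16). The sodium channel SCN1A rose by a log2 of 0.94 (adjusted p = 0.024) and the glutamate receptor subunits GRIA4 and GRIN2A by 0.78 (adjusted p = 0.025) and 0.67 (adjusted p = 0.034). TTR, made by the choroid plexus and the liver, stood at 304.6 in brain heat 2 and between 10466 and 23091 on the other brain arrays.

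HINTW, a gene of the female-specific W chromosome, was detected on the arrays of each group, with intensities of 2712 in muscle heat 1 to 10035 in brain heat 3. Its deviations from the group mean went together across tissues for arrays with the same number in a condition (exact permutation test over 1296 relabellings, one-sided, p = 0.0039). Within a condition, 5 of 36 relabellings went together as closely in controls and 1 of 36 in heat, so the agreement rested mostly on the heat arrays. Arrays of the same number holding RNA of the same birds across tissues, which the labels do not state, would give this agreement. HINTW was also highest on the array numbered 3 in each group, in controls and heat alike. Another factor that went with the number would give the same agreement, and the test cannot tell these apart.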
